A study of Arabidopsis thaliana with 47 samples.

How the data were processed

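RNA of whole Arabidopsis seedlings was hybridized to 47 Affymetrix ATH1 arrays, 1 per sample of pooled seedlings, and biological replicates were grown separately according to the descriptions of the study. The deposited value table holds 1 linear signal intensity per probe set and array. The submitters' processing notes name MAS5 and GCRMA without saying which made which table. From the values, each array had been scaled to a 2% trimmed mean near 500 (499.78 to 499.84), as MAS5 does, and the distributions had not been equalized between arrays. A second table deposited by the authors holds, per the file headers, log ratios between groups, read here as log2 because the base is not stated, and a p-value beside each ratio, whose test and adjustment are not stated. It holds comparisons only, so the comparisons could not be recomputed from it, although that had been foreseen. Detection calls were not used here, and the first quartile of each array was taken as a floor for dim signals, a choice made after the data were seen. In 54 of 189 gene results of 2 groups the mean of the dimmer group lay at or below the mean of this floor, and the text gives a bound. The ranking of the largest changes used no floor, and no bound was computed for differences between responses.

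Values were transformed to log2(signal + 1) and read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, figures were drawn with matplotlib 3.10.9, while tests were run in R 4.3.3 with limma 3.58.1. Of 22810 probe sets, 64 controls were left out of all tests and 22746 were tested. The annotation gave 21463 of these 1 gene, 503 several genes and 712 none, and for 68 the platform table and the genome annotation named different genes. Gene names came from the TAIR10.1 annotation, and no coordinates were used. A single limma fit of all 47 arrays had 12 cells: the 8 groups after the shift, and the 0 h group of each treatment as arrays 1 to 4 and 5 to 8. Adjusted p-values are Benjamini-Hochberg values within a comparison, and a call is an adjusted p under 0.05. The 17 comparisons were lincomycin against none at 5 times, each later time against 0 h in each treatment, and the difference between the light responses with and without lincomycin. The light responses of the treatments share no arrays.

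These choices, the gene lists and the rule for named genes were made before the data were examined. A rule of that kind also said which 0 h arrays would serve as reference: if a 2-cluster split of the spike-in controls followed the numbering in each treatment, the arrays of the same cluster as the later group would be the reference, and otherwise the mean of both sets. Only 12 of 16 arrays followed the numbering, so the mean of both 0 h sets was used. A split of the controls into 3 clusters, made after the data were seen, gave the labelling batches: the early arrays without lincomycin (0.5 and 1 h, and 0 h numbers 1 to 4), the early arrays with lincomycin, and the late arrays of both treatments (4 and 24 h, and 0 h numbers 5 to 8). As an exception, array 4 at 24 h without lincomycin fell with the early arrays without lincomycin (Dap 4.83). It was kept with its own time in the late batch in the fit of 47 arrays. Values within batches come from a fit with the batch as a term and 46 arrays. Lincomycin effects at 0 h then rest on numbers 5 to 8, those at 4 and 24 h on late arrays, light responses on the 0 h arrays of the same batch, and lincomycin effects at 0.5 and 1 h on the sum of such differences, which assumes that the difference between the 0 h sets is a batch difference.

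Gene lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, and adjusted over all 425 tests of 25 lists in 17 comparisons. Lists held nuclear genes of photosynthesis (photosystems and electron transport, antenna, Calvin cycle, photorespiration), pigments (tetrapyrroles, carotenoids), plastid ribosome and transcription, flavonoids, light signalling, photoprotection, heat shock, clock, shade and auxin growth, alternative respiration, defence, glucosinolates and the cell cycle, markers of roots, stomata, vessels and seeds, reference genes, and the plastid and mitochondrial genomes. Of the 20 antenna genes listed 12 had a probe set of their own, and of 19 Calvin cycle genes 15. A gene with several probe sets was represented by the one of highest mean, and probe sets of several genes were tested but not named. Named genes were the 5 largest rises and 5 largest falls among called probe sets with 1 gene whose higher group mean reached the median of all probe sets and whose groups of arrays did not overlap (no such condition for differences), up to 3 called members of each list discussed and 1 not called, and 11 fixed genes. For length, the text gives the first 3 of each 5 and fewer list members. For the differences at 0.5 and 1 h it gives those of the 5 whose call held within batches. This and the lists given at each time were chosen after their values were seen. Opposite responses were probe sets called in both treatments with opposite signs and called in the difference.

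Alternatives fixed in advance were quantile normalization, leaving out probe sets under percentile 40 of mean signal, log2(signal + 32), either 0 h set alone or all 8 arrays as 1 group, a fit of only the arrays compared, a block for the replicate number, and leaving out each array in turn. Leaving out the array apart (46 arrays), the batch term, and both together were added after seeing the data. In simulated data 200 of 22746 genes changed by 0.5, 1 or 2 log2 units. For the light response at 4 h the tests found 43.3%, 68.7% and 75.8%, with 5 false calls among 130. For the lincomycin effect at 4 h the shares were 31.3%, 58.2% and 72.7%, with 11 among 119. For the difference they were 9%, 46.3% and 77.3%, with 3 among 91. Shares in the fit of all arrays may be lower, because the array apart widens its spread.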

Results

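Transcript levels were measured on 47 ATH1 arrays of whole 7-day-old Arabidopsis thaliana Col-0 seedlings. Seedlings grew with or without 0.5 mM lincomycin, an antibiotic that blocks protein synthesis on plastid ribosomes, and stayed for 6 d in dim blue plus red light (0.5 µmol m-2 s-1). They were then moved to 60 µmol m-2 s-1 and collected after 0, 0.5, 1, 4 or 24 h. The 0 h groups held 8 arrays each, and the later groups 4 arrays each except for 3 arrays at 1 h with lincomycin. Changes are log2 differences between group means ± SE from a limma fit, and a probe set was called changed at an adjusted p under 0.05. The number of arrays limits the precision. Where the mean of the dimmer group lay at or below the mean first quartile of its arrays, the size of the change above that quartile is given as a bound (at least). Genes named as largest are those among genes whose brighter group reached the median signal of all probe sets and, except for differences between responses, whose groups of arrays did not overlap. In the lincomycin comparisons a rise or fall is relative to seedlings without lincomycin at the same time. Median signals ran from 179.4 to 245.1 across 46 arrays.

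The arrays carried differences that the labels did not name. The poly-A spike-in control Dap, added as RNA before labelling, averaged 4.31 ± 0.35 (log2 signal, SD, n = 12) on the arrays without lincomycin at 0.5 and 1 h and 0 h numbers 1 to 4. It averaged 9.04 ± 0.14 (n = 11) on the arrays with lincomycin of the same times and numbers. On the remaining arrays of both treatments (0 h numbers 5 to 8, 4 h and 24 h) it averaged 8.25 ± 0.25 (n = 23), with array 4 at 24 h without lincomycin (4.83) not counted. These 3 sets are called labelling batches here, and for each comparison the count from differences taken within batches is given beside the count from all arrays. Array 4 at 24 h without lincomycin stood apart from the others: its median rank correlation with all arrays was 0.618, against 0.915 to 0.949 for the other 46. Within-batch values leave that array out. Its plastid genome list averaged 13.36, against 11.38 to 11.72 on the others of its group. Organelle genome signals may thus depend on RNA quality or labelling.

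**Figure D1:**
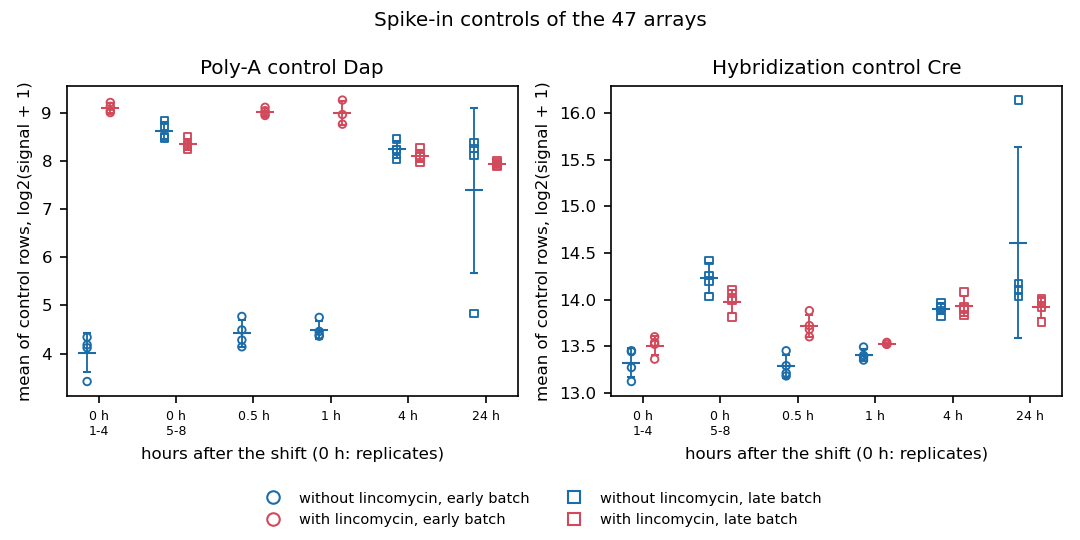
Log2 signal of the spike-in controls Dap and Cre on each array, by time point and treatment (circles, early batches; squares, late batch; blue without and red with lincomycin; horizontal marks, means). Dap averaged 4.31, 9.04 and 8.25 in the 3 sets with the array apart not counted, and that array lay at 4.83.

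The lincomycin comparison at 0 h asked which transcripts differed in low light when plastid translation was blocked (n = 8 and 8 arrays). Nuclear genes for photosynthesis were lower with lincomycin. The largest falls were those of LHCB2.3 (AT3G27690, -4.39 ± 0.20), CA1 (AT3G01500, -4.03 ± 0.20) and AT3G28270 (-3.98 ± 0.27, at least 2.53), of which LHCB2.3 encodes an antenna protein and CA1 a chloroplast carbonic anhydrase. Genes of quenching, carbon fixation and photorespiration fell with them: PSBS (AT1G44575, -2.87 ± 0.09), PRK (AT1G32060, -2.11 ± 0.08) and GS2 (AT5G35630, -1.98 ± 0.08), where PSBS serves non-photochemical quenching and GS2 reassimilates photorespiratory ammonium. The pigment genes BCH2 (AT5G52570, -2.92 ± 0.18) and CHLH (AT5G13630, -1.51 ± 0.11) fell, as did the regulators of photosynthetic genes GLK2 (AT5G44190, -2.37 ± 0.20), CGA1 (AT4G26150, -1.81 ± 0.14) and GLK1 (AT2G20570, -1.35 ± 0.21, within batches -0.66 ± 0.27, not called). The largest rises were those of UPOX (AT2G21640, 2.75 ± 0.17), AT2G43620 (2.69 ± 0.32) and LSH10 (AT2G42610, 2.41 ± 0.36). UPOX encodes a mitochondrial protein used as a stress marker. The defence genes PR2 (AT3G57260, 3.47 ± 0.48, at least 2.60) and PR5 (AT1G75040, 2.71 ± 0.37, at least 1.30), whose arrays overlapped between the groups and which were therefore not ranked, rose too, as did the mitotic cyclin CYCB1;1 (AT4G37490, 2.11 ± 0.21).

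By gene list at 0 h (camera tests), 31 of 31 photosystem and electron transport genes were lower (median -1.68, adjusted p = 1.4e-59) and 11 of 12 antenna genes were lower (median -1.33, adjusted p = 1.7e-18). Beyond these, 14 of 15 Calvin cycle genes were lower (median -1.46, adjusted p = 5.5e-21) and 11 of 11 photorespiration genes were lower (median -1.69, adjusted p = 5.4e-20). Among pigment and regulator lists, 1 were higher and 19 lower of 29 tetrapyrrole synthesis genes (median -0.66 and -0.38 within batches, adjusted p = 6e-14) and 11 of 17 carotenoid synthesis genes were lower (median -0.57, adjusted p = 7.1e-10). Beyond these, 18 of 26 light signalling genes were lower (median -0.54, adjusted p = 3.3e-11) and 2 were higher and 6 lower of 16 photoprotection and antioxidant genes (median -0.21 and -0.41 within batches, adjusted p = 0.00019). Further, 1 were higher and 8 lower of 16 circadian clock genes (median -0.47 and -0.74 within batches, adjusted p = 1.9e-06, adjusted p = 0.068 with an estimated correlation). For plastid gene expression, 24 of 27 plastid ribosome genes were lower (median -0.58 and -0.30 within batches, adjusted p = 1e-14) and 5 were higher and 6 lower of 16 plastid transcription genes (median -0.01, adjusted p = 0.038, adjusted p = 0.25 with an estimated correlation, not called within batches). Of 71 plastid genome genes 12 were higher and 31 lower (median -0.45, adjusted p = 6.1e-07, adjusted p = 0.37 with an estimated correlation). In the other direction, 7 of 7 cell cycle genes were higher (median 0.75, adjusted p = 0.00015) and 7 of 9 defence and jasmonate genes were higher (median 0.70 and 0.09 within batches, adjusted p = 0.001, adjusted p = 0.085 with an estimated correlation, not called within batches). Beyond these, 6 of 7 glucosinolate synthesis genes were higher (median 1.07, adjusted p = 0.001, adjusted p = 0.23 with an estimated correlation) and 6 of 7 vascular marker genes were higher (median 0.55, adjusted p = 0.016, adjusted p = 0.057 with an estimated correlation). Of other lists, 7 were higher and 1 lower of 11 alternative respiration genes (median 0.60, adjusted p = 0.078) and 2 were higher and 1 lower of 15 root marker genes (median 0.31, adjusted p = 0.9). Of 10 seed storage genes 1 was higher (median 0.49, adjusted p = 0.67). Counts adjusted over the list alone were, in the same order, 31, 11, 14, 11, 2 and 19, 12, 19, 2 and 6, 1 and 9, 26, 6 and 6, 12 and 31, 7, 8, 6, 6, 7 and 1, 2 and 1 and 1. In all, 7347 probe sets passed the threshold, 4906 higher and 2441 lower (7109 within batches and 4743 with 0 h numbers 5 to 8 alone). Higher probe sets made up 66.8% of these, and 54.4% after quantile scaling, which moved the median of all probe sets from 0.16 to 0.02.

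At 0.5 and 1 h after the shift the same comparison asked how the treatments differed early in brighter light (n = 4 and 4, then 3 and 4 arrays). The largest rises at 0.5 h were PR2 (6.42 ± 0.67, at least 4.97), AT5G10760 (5.62 ± 0.74, at least 3.26, within batches 2.36 ± 1.30, not called) and SAG13 (AT2G29350, 4.65 ± 0.90, at least 3.19, within batches 3.62 ± 1.56, not called). PR2 encodes a secreted glucanase and SAG13 is a marker of senescence. The largest falls at 0.5 h were LEA18 (AT2G35300, -4.26 ± 0.32, at least 2.64), LHCB2.3 (-4.10 ± 0.28) and CA1 (-3.88 ± 0.28), and LEA18 encodes a late embryogenesis abundant protein. At 1 h the largest rises were AT5G10760 (6.11 ± 0.80, at least 3.47, within batches 2.85 ± 1.34, not called), PR2 (5.78 ± 0.73, at least 4.95) and SAG13 (4.55 ± 0.97, at least 3.87, within batches 3.52 ± 1.60, not called), and the largest falls LEA18 (-4.33 ± 0.34, at least 3.37), BBX16 (AT1G73870, -4.21 ± 0.40, at least 3.54, within batches -2.79 ± 0.66) and CA1 (-4.05 ± 0.30). The plastid gene psbA (ATCG00020, -3.91 ± 0.32, within batches -2.45 ± 0.51) for the photosystem II core fell too. Photosynthesis genes stayed lower at 0.5 h, as for PSBS (-2.43 ± 0.12), BCH2 (-3.14 ± 0.26) and GLK1 (-3.16 ± 0.30, at least 2.88, within batches -1.79 ± 0.47), and at 1 h, as for PETE1 (AT1G76100, -2.27 ± 0.13), BCH2 (-3.43 ± 0.28) and GLK1 (-2.95 ± 0.32, within batches -1.58 ± 0.49). The flavonoid gene CHS (AT5G13930, 1.96 ± 0.53, within batches 4.84 ± 0.79) was higher at 0.5 h. At 1 h CHS (1.34 ± 0.58, adjusted p = 0.12, within batches 4.22 ± 0.81, called) was not past the threshold.

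By list at 0.5 h, 31 of 31 photosystem and electron transport genes were lower (median -1.65, adjusted p = 3.2e-60) and 1 were higher and 11 lower of 12 antenna genes (median -1.32, adjusted p = 1.1e-14). Beyond these, 1 were higher and 20 lower of 29 tetrapyrrole synthesis genes (median -0.81 and -0.40 within batches, adjusted p = 4.8e-17) and 20 of 27 plastid ribosome genes were lower (median -0.59 and -0.21 within batches, adjusted p = 1.7e-18). Further, 3 were higher and 5 lower of 16 plastid transcription genes (median 0.04 and -0.08 within batches, adjusted p = 0.028, adjusted p = 0.22 with an estimated correlation, not called within batches, median -0.16 after quantile scaling, mean -0.16). Camera placed the plastid transcription list lower although its median was above 0. Of other lists at 0.5 h, 8 of 9 defence and jasmonate genes were higher (median 1.13 and 0.30 within batches, adjusted p = 7.8e-06, not called within batches) and 8 of 28 mitochondrial genome genes were higher (median 0.73 and -0.12 within batches, adjusted p = 0.037, adjusted p = 0.67 with an estimated correlation, not called within batches, not called after quantile scaling). At 1 h, 31 of 31 photosystem and electron transport genes were lower (median -1.55, adjusted p = 2.1e-60) and 11 of 12 antenna genes were lower (median -1.26, adjusted p = 2.9e-16). Beyond these, 16 of 27 plastid ribosome genes were lower (median -0.62 and -0.10 within batches, adjusted p = 4e-17, not called within batches) and 8 of 9 defence and jasmonate genes were higher (median 1.29 and 0.20 within batches, adjusted p = 9.2e-08). Further, 4 of 7 vascular marker genes were higher (median 0.53, adjusted p = 0.017, adjusted p = 0.059 with an estimated correlation). Taking lists in that order, the counts adjusted over the list alone were 31, 1 and 11, 1 and 20, 24, 3 and 5, 8, 8, 31, 11, 22, 9 and 5. At 0.5 h 4987 probe sets passed the threshold, 3100 higher and 1887 lower (3251 within batches), with 62.2% higher, or 51.2% after quantile scaling. At 1 h 3649 probe sets passed the threshold, 2133 higher and 1516 lower (2984 within batches, and 5768 without the array apart). Quantile scaling moved the median of all probe sets from 0.22 to 0.03 at 0.5 h and from 0.14 to 0.03 at 1 h.

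At 4 h, when all compared arrays belonged to 1 labelling batch (n = 4 and 4), falls were largest for AT3G28270 (-5.67 ± 0.39), CA1 (-5.46 ± 0.28) and LHCB2.3 (-4.75 ± 0.28). Light-harvesting and electron-transport genes such as LHCB6 (AT1G15820, -2.93 ± 0.43), PSBQ2 (AT4G05180, -2.86 ± 0.20) and PETE1 (-2.61 ± 0.12) fell, and so did PORA (AT5G54190, -3.02 ± 0.51, at least 1.32) and PORB (AT4G27440, -2.39 ± 0.19), which reduce protochlorophyllide in the light. The regulators GLK2 (-3.20 ± 0.28) and GLK1 (-3.05 ± 0.30) fell, while the light-signalling factor HY5 (AT5G11260, 0.63 ± 0.18) rose. The largest rises were AT5G55450 (5.84 ± 0.48, at least 2.21), AT3G05730 (3.79 ± 0.44) and AT3G24750 (3.25 ± 0.56). The anthocyanin regulator TT8 (AT4G09820, 4.10 ± 0.66, at least 0.67), too dim to be ranked, rose as well, whereas CHS (0.74 ± 0.53, adjusted p = 0.45) and ELIP1 (AT3G22840, 1.17 ± 0.44, adjusted p = 0.071, without the array apart 1.17 ± 0.44, called) did not pass the test. The stomatal lineage regulator SPCH (AT5G53210, -2.47 ± 0.58, at least 1.80) fell, and so did the jasmonate enzyme LOX2 (AT3G45140, -2.45 ± 0.38). By list, 30 of 31 photosystem and electron transport genes were lower (median -1.70, adjusted p = 9.2e-72) and 11 of 12 antenna genes were lower (median -1.70, adjusted p = 3e-25). Beyond these, 1 were higher and 14 lower of 29 tetrapyrrole synthesis genes (median -0.68, adjusted p = 1.4e-15) and 7 of 27 plastid ribosome genes were lower (median -0.26, adjusted p = 0.00026, adjusted p = 0.23 with an estimated correlation). Among the rest, 10 of 22 flavonoid and anthocyanin genes were higher (median 0.64, adjusted p = 8.6e-05) and 4 of 7 vascular marker genes were higher (median 0.62, adjusted p = 0.00011). Again in order, the counts adjusted over the list alone were 31, 11, 1 and 19, 7, 12 and 4. In total 3155 probe sets passed the threshold, 1834 higher and 1321 lower. Leaving out the array apart, which is in neither group but enters the shared estimate of the spread, gave 5143.

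At 24 h the comparison asked how the treatments differed after a day in brighter light (n = 4 and 4 arrays). The largest rises were SEN1 (AT4G35770, 4.32 ± 0.16), BCAT-2 (AT1G10070, 4.27 ± 0.23) and UPOX (4.26 ± 0.24), where SEN1 responds to darkness and low sugar and BCAT-2 breaks down branched-chain amino acids. Largest among the falls were AT1G13650 (-6.91 ± 0.69, at least 3.77), BBX16 (-5.47 ± 0.37, at least 3.22) and AT5G48490 (-5.31 ± 0.25). Photosystem and chlorophyll genes fell, with PSAD2 (AT1G03130, -4.65 ± 0.17), PETE1 (-4.17 ± 0.12), LHCB3 (AT5G54270, -3.64 ± 0.11) and PORB (-3.91 ± 0.19). The plastid ribosomal protein PRPL18 (AT1G48350, -1.71 ± 0.15) fell, and so did genes of dividing cells and stomata, PCNA1 (AT1G07370, -1.60 ± 0.19) and SPCH (-2.55 ± 0.58, at least 1.65). The glucosinolate gene BCAT4 (AT3G19710, -2.34 ± 0.30) and the jasmonate enzyme LOX2 (-3.77 ± 0.38) fell too. Light-signalling and clock genes RUP1 (AT5G52250, 1.83 ± 0.18), HY5 (1.20 ± 0.18), PRR5 (AT5G24470, 1.28 ± 0.15) and SIG5 (AT5G24120, 1.32 ± 0.23, without the array apart 0.86 ± 0.14) rose. Rubisco activase did not pass the test with all arrays, RCA (AT2G39730, -0.01 ± 0.45, adjusted p = 0.99, without the array apart -1.10 ± 0.10, called). By list, 31 of 31 photosystem and electron transport genes were lower (median -2.55, adjusted p = 4.4e-50) and 11 of 12 antenna genes were lower (median -2.66, adjusted p = 5.4e-19). Beyond these, 1 were higher and 24 lower of 29 tetrapyrrole synthesis genes (median -1.22, adjusted p = 1.9e-16) and 22 of 27 plastid ribosome genes were lower (median -1.26, adjusted p = 2.3e-20). Further, 5 were higher and 45 lower of 71 plastid genome genes (median -1.22 and -0.48 without the array apart, adjusted p = 2.3e-09, adjusted p = 0.27 with an estimated correlation). Outside the plastid, 15 were higher and 2 lower of 26 light signalling genes (median 0.40, adjusted p = 0.00053, adjusted p = 0.11 with an estimated correlation, not called without the array apart) and 1 were higher and 5 lower of 7 cell cycle genes (median -0.99, adjusted p = 0.0071, adjusted p = 0.068 with an estimated correlation). Beyond these, 4 of 6 stomatal and guard cell marker genes were lower (median -1.31, adjusted p = 0.026, adjusted p = 0.06 with an estimated correlation). For these lists the counts adjusted over the list alone were 31, 12, 1 and 25, 25, 5 and 47, 15 and 2, 1 and 5 and 4. In total 7532 probe sets passed the threshold, 4516 higher and 3016 lower, against 1574 in a fit of only the arrays compared, and 7321 without the array apart. Quantile scaling moved the median of all probe sets from -0.07 to 0.03.

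The light response without lincomycin asked which transcripts changed when seedlings moved from dim to brighter light (0.5 and 1 h, n = 4 arrays each against 8 at 0 h). At 0.5 h the cytokinin-response regulator ARR15 (AT1G74890, 3.51 ± 0.30), the cold-response factor DREB1A (AT4G25480, 2.89 ± 0.26) and AT3G52740 (2.37 ± 0.30, at least 1.92) gave the largest rises. The largest falls were AT4G34770 (-4.48 ± 0.44, at least 2.53), SAUR23 (AT5G18060, -3.50 ± 0.28) and AT2G17880 (-2.58 ± 0.43, at least 2.15), of which SAUR23 belongs to the small auxin-induced RNAs. The shade factor HAT1 (AT4G17460, -2.16 ± 0.30, at least 1.76) fell and the light-signalling genes CGA1 (1.84 ± 0.18) and HY5 (1.15 ± 0.15) rose. At 1 h the largest rises were AT2G15020 (4.06 ± 0.50, at least 3.08), AT5G42760 (4.05 ± 0.49, at least 3.75) and ATGA2OX1 (AT1G78440, 3.94 ± 0.34, at least 2.35), of which ATGA2OX1 inactivates gibberellin, and the largest falls AT5G50335 (-4.33 ± 0.60, at least 2.49), AT4G34770 (-4.07 ± 0.44, at least 2.50) and AT2G17880 (-3.46 ± 0.43, at least 2.32). By 1 h the early light-induced proteins ELIP1 (2.99 ± 0.38) and ELIP2 (AT4G14690, 2.91 ± 0.26), the sigma factor SIG5 (1.83 ± 0.20) and the regulators HY5 (2.42 ± 0.15) and RUP2 (AT5G23730, 2.46 ± 0.26) had risen, and the shade factor ATHB2 (AT4G16780, -2.80 ± 0.38) had fallen.

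By list at 0.5 h, 7 of 20 shade and auxin growth genes fell (median -0.55, adjusted p = 7.5e-08) and 10 rose and 1 fell of 26 light signalling genes (median 0.32 and 0.16 within batches, adjusted p = 1.6e-06). Beyond these, 6 rose and 1 fell of 22 flavonoid and anthocyanin genes (median 0.50 and 0.18 within batches, adjusted p = 0.0051, adjusted p = 0.072 with an estimated correlation, not called within batches). At 1 h, 1 rose and 10 fell of 20 shade and auxin growth genes (median -0.66, adjusted p = 6.3e-09) and 14 rose and 4 fell of 26 light signalling genes (median 0.48, adjusted p = 1.5e-08). Beyond these, 8 rose and 1 fell of 22 flavonoid and anthocyanin genes (median 0.87 and 0.40 within batches, adjusted p = 1.4e-05) and 9 of 16 photoprotection and antioxidant genes rose (median 0.40 and 0.21 within batches, adjusted p = 2.2e-05). The counts adjusted over the list alone, again in order, were 10, 14 and 2, 7 and 2, 1 and 12, 15 and 5, 9 and 1 and 9. At 0.5 h 1775 probe sets passed the threshold, 983 higher and 792 lower. The count was 399 within batches and 3695 without the array apart, 1004 without array 1 and 1157 without array 3 of the 0.5 h group. It was 164 or 5487 with 0 h numbers 1 to 4 or 5 to 8 alone, and 3151 in a fit of only the arrays compared. At 1 h 3629 probe sets passed the threshold, 1935 higher and 1694 lower, with 2108 within batches and 5962 without the array apart. Numbers 1 to 4 or 5 to 8 alone gave 1147 or 6669, and only the arrays compared 5653.

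At 4 h without lincomycin (n = 4 arrays against 8) the largest rises were CHS (5.41 ± 0.46), MSRB6 (AT4G04840, 5.19 ± 0.30) and ELIP1 (5.10 ± 0.38). CHS encodes the first enzyme of flavonoid synthesis, MSRB6 a methionine sulfoxide reductase and ELIP1 a chlorophyll-binding protein of the thylakoid. The largest falls were those of SIS (AT5G02020, -4.77 ± 0.16), BCAT-2 (-4.65 ± 0.20) and AT5G44260 (-4.61 ± 0.33). Heat-shock and oxidative-stress genes HSP17.4 (AT3G46230, 4.07 ± 0.37), HSFA2 (AT2G26150, 3.48 ± 0.46, at least 2.21) and GPX7 (AT4G31870, 3.20 ± 0.38) rose. Chlorophyll and carotenoid enzymes DVR (AT5G18660, 2.22 ± 0.22) and LUT1 (AT3G53130, 1.78 ± 0.12) and the plastid RNA polymerase RPOTP (AT2G24120, 2.38 ± 0.23) rose, as did PSBS (1.49 ± 0.11) and GLDP1 (AT4G33010, 2.45 ± 0.26), which act in quenching and photorespiration. Shade and clock genes IAA29 (AT4G32280, -3.24 ± 0.34) and RVE1 (AT5G17300, -2.87 ± 0.13) fell. By list, 12 of 18 heat shock genes rose (median 2.10, adjusted p = 4e-08) and 14 rose and 1 fell of 22 flavonoid and anthocyanin genes (median 1.19, adjusted p = 1.2e-06). Beyond these, 13 of 16 plastid transcription genes rose (median 1.12, adjusted p = 1.3e-08) and 11 of 17 carotenoid synthesis genes rose (median 0.71, adjusted p = 1.9e-06). Further, 10 of 16 photoprotection and antioxidant genes rose (median 0.55, adjusted p = 0.00021). Of the photosynthesis and plastid ribosome lists, 20 of 31 photosystem and electron transport genes rose (median 0.39, adjusted p = 7.7e-05, adjusted p = 0.05 with an estimated correlation) and 5 rose and 1 fell of 11 photorespiration genes (median 0.39 and 0.11 within batches, adjusted p = 0.039, adjusted p = 0.48 with an estimated correlation, not called within batches). Beyond these, 9 of 27 plastid ribosome genes rose (median 0.19 and 0.36 within batches, adjusted p = 0.039, adjusted p = 0.52 with an estimated correlation). Lower values came from other lists, where 1 rose and 15 fell of 20 shade and auxin growth genes (median -1.32, adjusted p = 3e-06) and 5 of 8 reference genes fell (median -0.40, adjusted p = 0.047, adjusted p = 0.082 with an estimated correlation). At 4 h the counts adjusted over the list alone were 14, 14 and 1, 14, 13, 10 and 1, 20, 5 and 2, 9, 1 and 15 and 5. In total 8853 probe sets passed the threshold, 4496 higher and 4357 lower (9470 within batches).

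At 24 h without lincomycin (n = 4 arrays against 8) the largest rises were AT1G13650 (6.50 ± 0.60, at least 3.74), CRK21 (AT4G23290, 5.57 ± 0.55, at least 3.73) and AT2G36145 (5.46 ± 0.26), where CRK21 encodes a receptor-like kinase. The largest falls were AT5G39520 (-6.15 ± 0.27, at least 4.44), RAB18 (AT5G66400, -6.09 ± 0.19) and BCAT-2 (-5.78 ± 0.20), and RAB18 is a dehydrin induced by abscisic acid. Photosynthesis and chlorophyll genes FNR2 (AT1G20020, 2.98 ± 0.12), LHCB4.3 (AT2G40100, 3.01 ± 0.19), DVR (4.42 ± 0.22) and SBPASE (AT3G55800, 2.66 ± 0.09) rose. The plastid ribosomal protein PRPL18 (2.36 ± 0.13), the glucosinolate gene CYP83A1 (AT4G13770, 3.50 ± 0.36) and the replication factor PCNA1 (1.83 ± 0.17) rose too. PHYA (AT1G09570, -2.76 ± 0.23) and ACT2 (AT3G18780, -1.60 ± 0.10) fell, which encode a photoreceptor of low light and an actin. Some fixed genes depended on the array apart, which read low for them: RCA (0.19 ± 0.39, adjusted p = 0.72, within batches 1.59 ± 0.10, called), GUN4 (AT3G59400, 0.06 ± 0.35, adjusted p = 0.9, within batches 1.43 ± 0.13, called) and HEMA1 (AT1G58290, 0.16 ± 0.21, adjusted p = 0.55, within batches 1.13 ± 0.12, called). Without that array alone the values were 1.28, 1.02 and 0.69, all past the threshold. By list, 26 of 31 photosystem and electron transport genes rose (median 1.36, adjusted p = 1e-15) and 9 of 12 antenna genes rose (median 0.95, adjusted p = 4.8e-05). Beyond these, 9 of 15 Calvin cycle genes rose (median 0.90 and 1.59 within batches, adjusted p = 2.8e-05, adjusted p = 0.14 with an estimated correlation) and 16 of 17 carotenoid synthesis genes rose (median 1.01, adjusted p = 8.1e-09). Further, 24 of 27 plastid ribosome genes rose (median 1.64, adjusted p = 3.9e-17) and 36 of 71 plastid genome genes rose (median 0.60 and 0.34 within batches, adjusted p = 0.00016, adjusted p = 0.51 with an estimated correlation). Beyond the plastid, 13 rose and 2 fell of 22 flavonoid and anthocyanin genes (median 1.64, adjusted p = 0.00017) and 7 of 7 cell cycle genes rose (median 1.14, adjusted p = 0.00071). Beyond these, 1 rose and 5 fell of 8 reference genes (median -0.67 and -0.38 within batches, adjusted p = 0.016). After 24 h the counts adjusted over the list alone were 26, 10, 10, 16, 25, 37, 14 and 2, 7 and 1 and 5. In total 11117 probe sets passed the threshold, 5764 higher and 5353 lower (9947 within batches). The median of all probe sets was 0.14, and 0.01 after quantile scaling.

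The light response with lincomycin asked which of these changes took place when plastid translation was blocked (0.5 h, n = 4, and 1 h, n = 3, against 8 arrays at 0 h). At 0.5 h DREB1A (2.02 ± 0.26, within batches 1.12 ± 0.24), BBX31 (AT3G21890, 1.90 ± 0.16) and AT3G12320 (1.63 ± 0.11, within batches 0.59 ± 0.12) gave the largest rises, among them the B-box factor BBX31. Falls were largest for AT4G34770 (-2.68 ± 0.44, at least 2.03), ATHB2 (-2.10 ± 0.38) and SAUR23 (-1.64 ± 0.28). Regulators of greening and light signalling, CGA1 (1.49 ± 0.18) and HY5 (1.02 ± 0.15), and the sigma factor SIG5 (1.49 ± 0.20) rose within 0.5 h. At 1 h the largest rises were ATGA2OX1 (3.74 ± 0.38, at least 2.42), FADA (AT4G27030, 3.66 ± 0.40, at least 2.35) and AT3G52740 (3.43 ± 0.33, at least 2.59), and the largest falls SAUR23 (-3.11 ± 0.31, at least 2.54), IAA29 (-2.70 ± 0.37) and AT4G34770 (-2.57 ± 0.49, at least 2.08). SIG5 (3.09 ± 0.22), ELIP1 (3.07 ± 0.42), HY5 (2.83 ± 0.17) and PSBS (1.59 ± 0.12) had risen by then. The clock gene GI (AT1G22770, 1.64 ± 0.21) rose too. The defence gene PR1 (AT2G14610, 2.09 ± 0.46, within batches 0.40 ± 0.50, not called) was higher with all arrays.

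By list at 0.5 h, 9 rose and 2 fell of 26 light signalling genes (median 0.32 and 0.17 within batches, adjusted p = 9e-08) and 5 of 22 flavonoid and anthocyanin genes rose (median 0.57, adjusted p = 0.00082). Beyond these, 3 of 20 shade and auxin growth genes fell (median -0.20 and -0.41 within batches, adjusted p = 0.00091) and 7 of 16 circadian clock genes rose (median 0.45 and 0.19 within batches, adjusted p = 6.4e-06, adjusted p = 0.085 with an estimated correlation). At 1 h, 12 rose and 1 fell of 26 light signalling genes (median 0.48 and 0.27 within batches, adjusted p = 7.2e-21) and 6 of 22 flavonoid and anthocyanin genes rose (median 0.76, adjusted p = 1.3e-11). Beyond these, 6 of 16 photoprotection and antioxidant genes rose (median 0.69 and 0.39 within batches, adjusted p = 1.9e-09) and 9 of 16 circadian clock genes rose (median 0.60 and 0.21 within batches, adjusted p = 7.8e-14). Further, 7 of 20 shade and auxin growth genes fell (median -0.64, adjusted p = 1.9e-11). Their counts adjusted over the list alone were 13 and 2, 6, 3, 8, 14 and 1, 10, 9, 11 and 11. At 0.5 h 1290 probe sets passed the threshold, 684 higher and 606 lower, against 206 within batches, 3108 without the array apart and 710 without array 4 of the 0.5 h group. Numbers 1 to 4 or 5 to 8 of 0 h alone gave 64 or 4752 at 0.5 h, and 286 or 3743 at 1 h. At 1 h 1062 probe sets passed the threshold, 602 higher and 460 lower, against 675 within batches, 2546 without the array apart, and 593 and 670 without array 1 or array 2 of the 1 h group.

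At 4 h with lincomycin (n = 4 arrays against 8) the largest rises were ELIP1 (5.69 ± 0.38), FADA (5.62 ± 0.36, at least 4.32) and UGT84A1 (AT4G15480, 5.38 ± 0.55, at least 2.82), where FADA encodes a plastid desaturase and UGT84A1 a glycosyltransferase of hydroxycinnamates. Flavonoid enzymes F3H (AT3G51240, 4.95 ± 0.22) and CHS (4.34 ± 0.46) and heat-shock proteins HSP17.4 (3.82 ± 0.37, at least 3.49) and HSP101 (AT1G74310, 2.98 ± 0.24) rose, and so did PSBS (3.22 ± 0.11) and GLDP1 (2.57 ± 0.26) of quenching and photorespiration. The nuclear factors SIG5 (3.13 ± 0.20), HYH (AT3G17609, 3.28 ± 0.15) and CGA1 (3.08 ± 0.18) rose, which act in plastid transcription, light signalling and greening. The largest falls were DIN11 (AT3G49620, -4.69 ± 0.68, at least 2.32), AT5G50335 (-3.66 ± 0.60) and GH3.3 (AT2G23170, -3.28 ± 0.31, at least 3), where DIN11 is induced by darkness and GH3.3 conjugates auxin. PORA (-2.97 ± 0.45, at least 1.26) fell as well. By list, 18 rose and 1 fell of 22 flavonoid and anthocyanin genes (median 1.70, adjusted p = 1.7e-18) and 13 of 18 heat shock genes rose (median 1.55, adjusted p = 5.3e-14). Beyond these, 15 of 16 plastid transcription genes rose (median 1.04, adjusted p = 7.7e-16) and 20 of 27 plastid ribosome genes rose (median 0.54, adjusted p = 1.2e-11). Further, 9 of 11 photorespiration genes rose (median 0.92, adjusted p = 5.4e-11) and 16 rose and 2 fell of 31 photosystem and electron transport genes (median 0.40, adjusted p = 1.4e-07). On the lower side, 16 of 20 shade and auxin growth genes fell (median -0.99, adjusted p = 3.8e-09) and 6 of 9 defence and jasmonate genes fell (median -0.93 and -0.42 within batches, adjusted p = 0.0017, adjusted p = 0.1 with an estimated correlation). With lincomycin at 4 h the counts adjusted over the list alone were 19 and 1, 13, 15, 20, 9, 18 and 4, 17 and 8. In total 5693 probe sets passed the threshold, 2416 higher and 3277 lower (4956 within batches, and 2860 with 0 h numbers 5 to 8 alone).

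At 24 h with lincomycin (n = 4 arrays against 8) FADA (5.59 ± 0.36, at least 4.29), AT2G36145 (4.85 ± 0.26, at least 3.70) and AT5G42760 (4.83 ± 0.49, at least 3.20) gave the largest rises. Photorespiration and Calvin cycle genes SHM1 (AT4G37930, 2.82 ± 0.09), CAT2 (AT4G35090, 1.96 ± 0.30), FBA2 (AT4G38970, 2.24 ± 0.25) and RCA (1.70 ± 0.39) rose, as did the plastid ribosomal protein PRPL24 (AT5G54600, 1.27 ± 0.12) and SIG5 (3.15 ± 0.20) and CHS (4.07 ± 0.46). The largest falls were AT5G50335 (-5.18 ± 0.60, at least 3.74), AT5G44440 (-4.64 ± 0.34, at least 3.22) and ST2A (AT5G07010, -4.52 ± 0.34, at least 3.89), of which ST2A sulfates jasmonates. The chlorophyll enzymes PORA (-2.62 ± 0.45, at least 1.25) and PORB (-2.05 ± 0.17) fell, with the auxin gene IAA5 (AT1G15580, -3.01 ± 0.51, at least 0.92), the jasmonate enzyme LOX2 (-2.55 ± 0.33) and the cytokinesis gene KNOLLE (AT1G08560, -0.78 ± 0.11). By list, 15 of 16 plastid transcription genes rose (median 1.26, adjusted p = 3.1e-17) and 24 of 27 plastid ribosome genes rose (median 0.93, adjusted p = 7.2e-21). Beyond these, 9 of 11 photorespiration genes rose (median 1.64, adjusted p = 2.3e-12) and 12 rose and 1 fell of 15 Calvin cycle genes (median 1.29, adjusted p = 3.9e-11). Further, 17 rose and 5 fell of 31 photosystem and electron transport genes (median 0.59, adjusted p = 9.6e-09) and 15 of 22 flavonoid and anthocyanin genes rose (median 1.43, adjusted p = 3.3e-11). Of the remaining lists, 14 of 20 shade and auxin growth genes fell (median -1.21, adjusted p = 1.2e-07) and 6 of 7 vascular marker genes fell (median -0.71, adjusted p = 0.0016). Beyond these, 7 of 9 defence and jasmonate genes fell (median -1.06, adjusted p = 7.5e-05) and 1 rose and 5 fell of 7 cell cycle genes (median -0.57, adjusted p = 0.074). Of 12 antenna genes 3 rose and 3 fell (median -0.04, adjusted p = 0.68, mean 0.11). With lincomycin at 24 h the counts adjusted over the list alone were 15, 25, 10, 12 and 2, 18 and 5, 15, 15, 7, 8, 1 and 5 and 3 and 3. In total 7201 probe sets passed the threshold, 2864 higher and 4337 lower (6943 within batches). The median of all probe sets was -0.14, or -0.02 after quantile scaling.

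The difference between the light responses, with minus without lincomycin, asked which responses depended on plastid translation. At 0.5 h (n = 4 arrays per treatment, 8 at 0 h) the cytokinin-response regulator ARR15 (-3.14 ± 0.42) and LEA18 (-2.64 ± 0.39) and AT1G75580 (-2.10 ± 0.33) had negative differences, and AT3G07350 (1.57 ± 0.23) and LBD37 (AT5G67420, 1.56 ± 0.19) positive ones, LBD37 being a repressor of nitrogen-responsive genes. At 1 h LEA18 (-2.70 ± 0.41), ARR15 (-2.57 ± 0.44) and AT3G48460 (-2.22 ± 0.15) had negative differences and the light-signalling factor GATA2 (AT2G45050, 2.30 ± 0.37) a positive one. These are the genes among the 5 of largest difference in each direction whose call held within batches, a choice made after their values were seen. LEA18 was dim with lincomycin at 0.5 and 1 h, so the sizes of its differences are uncertain. The quenching protein PSBS (1.17 ± 0.16) and the clock factor RVE1 (1.67 ± 0.19, within batches 1.04 ± 0.21) had positive differences at 1 h. The regulator GLK1 (-1.81 ± 0.36, within batches -1.12 ± 0.39, not called) had a negative difference at 0.5 h. By list at 0.5 h, 1 of 12 antenna genes had positive differences (median 0.32 and 0.21 within batches, adjusted p = 0.0026, adjusted p = 0.12 with an estimated correlation). At 1 h, 3 positive and 1 negative differences were found among 26 light signalling genes (median 0.18, adjusted p = 0.016, adjusted p = 0.28 with an estimated correlation) and 1 of 16 circadian clock genes had positive differences (median 0.18 and -0.03 within batches, adjusted p = 0.00042, adjusted p = 0.19 with an estimated correlation, not called within batches). Beyond these, 1 of 31 photosystem and electron transport genes had positive differences (median 0.14, adjusted p = 0.021, adjusted p = 0.26 with an estimated correlation, not called after quantile scaling). For the differences, the counts adjusted over the list alone were 4, 5 and 3, 1 and 1. At 0.5 h 196 probe sets passed the threshold, 82 higher and 114 lower, against 42 within batches and 891 without the array apart. Leaving out array 4 with lincomycin at 0.5 h gave 103, and leaving out array 1 or 2 without lincomycin at 0.5 h gave 110 or 127. At 1 h 477 probe sets passed the threshold, 234 higher and 243 lower, against 306 within batches, 1217 without the array apart, 286 after quantile scaling, and 308 or 298 without array 2 or 4 with lincomycin at 1 h. Numbers 1 to 4 or 5 to 8 of 0 h alone gave 14 or 1215 at 0.5 h and 64 or 1313 at 1 h. Fits of only the arrays compared gave 410 and 869, and leaving out dim probe sets gave 331 at 0.5 h.

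At 4 h (n = 4 arrays per treatment, 8 at 0 h) the senescence regulator NAP was among the largest positive differences, NAP (AT1G69490, 4.01 ± 0.46), AT5G18600 (3.07 ± 0.19) and AT2G17880 (2.92 ± 0.60). The largest negative differences were AT5G03350 (-4.27 ± 0.62), AT2G27420 (-4.01 ± 0.80) and LOX2 (-3.83 ± 0.46). The quenching protein PSBS (1.73 ± 0.15), the clock factor RVE1 (2.69 ± 0.18) and the light-signalling genes HYH (1.46 ± 0.22) and HY5 (1.21 ± 0.22, within batches 0.68 ± 0.23) had positive differences too. Chlorophyll enzymes PORA (-2.36 ± 0.63) and PORB (-1.37 ± 0.23), the regulator GLK1 (-1.70 ± 0.36), the glucosinolate regulator MYB28 (AT5G61420, -1.33 ± 0.25) and SPCH (-2.51 ± 0.71, -1.98, not called, without array 1 at 4 h with lincomycin) had negative ones. PORA was dim at 4 h with lincomycin, where its fall was at least 1.26, so the size of its difference is uncertain. By list, 7 of 16 circadian clock genes had positive differences (median 0.50 and 0.86 within batches, adjusted p = 2.2e-08) and 10 positive and 1 negative differences were found among 26 light signalling genes (median 0.53, adjusted p = 5.1e-07). Of 9 defence and jasmonate genes 4 had negative differences (median -0.77 and -0.40 within batches, adjusted p = 0.00017). Here the counts adjusted over the list alone were 9, 14 and 3 and 5. In total 2869 probe sets passed the threshold, 1283 higher and 1586 lower, against 4346 within batches, 4859 without the array apart and 4647 with only the arrays compared.

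At 24 h (n = 4 arrays per treatment, 8 at 0 h) the largest positive differences were SEN1 (5.94 ± 0.20), BCAT-2 (5.65 ± 0.28) and ASN1 (AT3G47340, 5.40 ± 0.20), and AT1G13650 (-7.00 ± 0.85), AT2G25510 (-6.18 ± 0.58) and LOX2 (-5.15 ± 0.46) were the largest negative ones. Genes of photosystems and chlorophyll, PSAD2 (-2.71 ± 0.20), LHCB3 (-1.79 ± 0.14) and PORB (-2.89 ± 0.23), of glucosinolates, BCAT4 (-3.79 ± 0.36), and of cell division and stomata, PCNA1 (-2.40 ± 0.24) and MUTE (AT3G06120, -2.85 ± 0.75), had negative differences. The light-signalling, clock and photorespiration genes CGA1 (3.36 ± 0.25), RVE1 (2.36 ± 0.18) and CAT2 (2.65 ± 0.43) and the actin ACT2 (1.33 ± 0.15) had positive ones. By list, 20 positive and 1 negative differences were found among 26 light signalling genes (median 0.70, adjusted p = 2.4e-12) and 13 positive and 1 negative differences were found among 16 circadian clock genes (median 1.15, adjusted p = 1.1e-09). Of 8 reference genes 4 had positive and 1 negative differences (median 0.50, adjusted p = 0.013). In the other direction, 6 of 7 cell cycle genes had negative differences (median -1.66, adjusted p = 5.9e-06) and 18 of 31 photosystem and electron transport genes had negative differences (median -0.76, adjusted p = 3.5e-08). Beyond these, 1 positive and 7 negative differences were found among 12 antenna genes (median -1.05, adjusted p = 0.00021, adjusted p = 0.057 with an estimated correlation) and 14 of 27 plastid ribosome genes had negative differences (median -0.54 and -1.02 within batches, adjusted p = 1.8e-06, adjusted p = 0.11 with an estimated correlation). At the last time point the counts adjusted over the list alone were 22 and 1, 13 and 1, 4 and 1, 6, 19, 1 and 8 and 16. In total 7118 probe sets passed the threshold, 3278 higher and 3840 lower (6844 within batches). The median of all probe sets was -0.26, and -0.001 after quantile scaling.

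**Figure D2:**
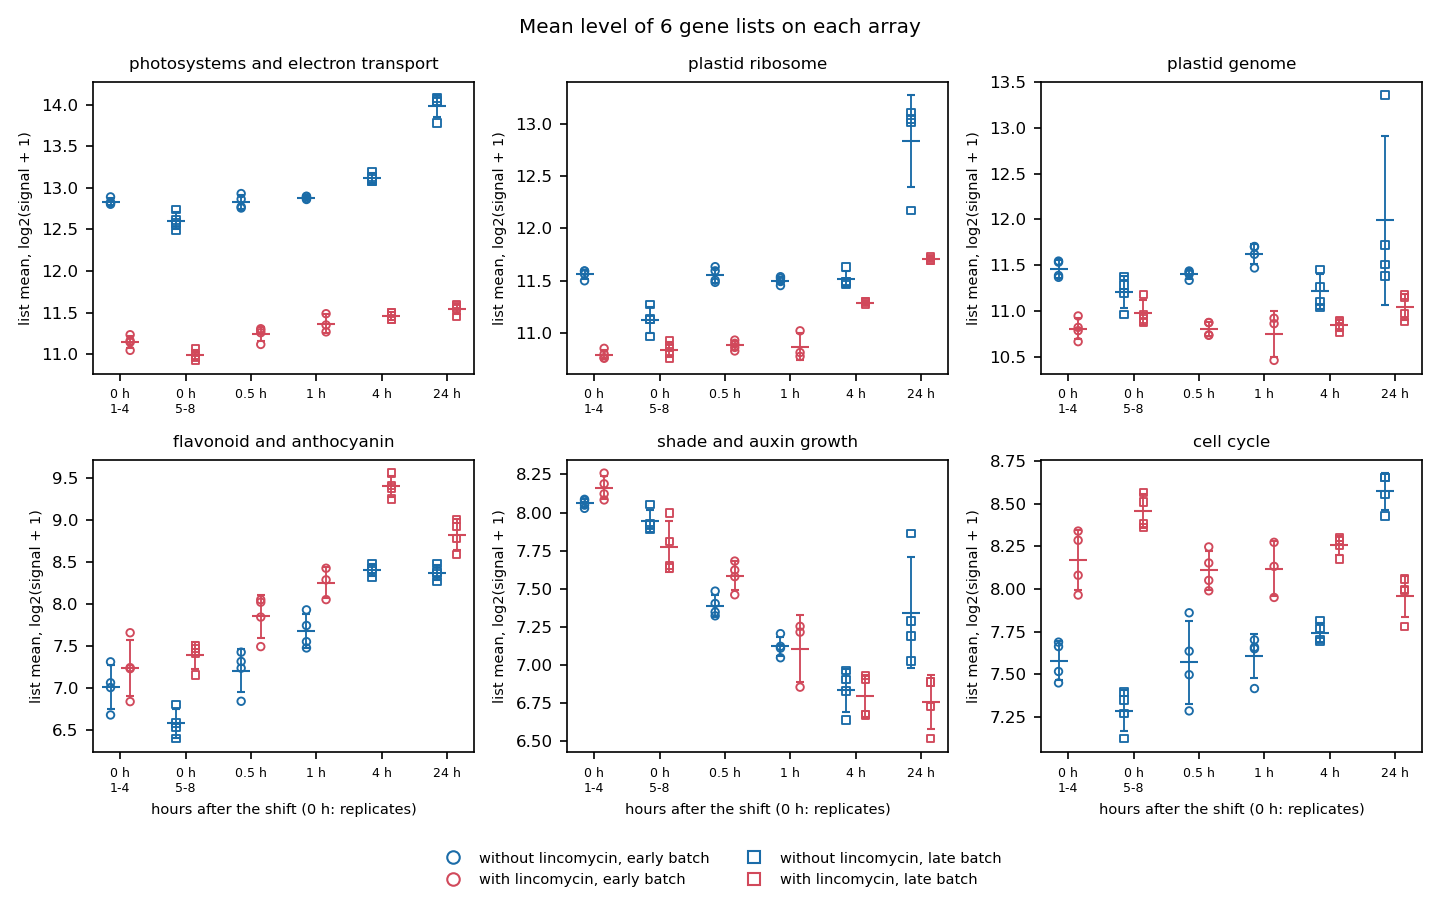
Mean log2 signal of 6 gene lists on each array by time point, with 0 h numbers 1-4 and 5-8 apart (circles, early batches; squares, late batch; blue without and red with lincomycin; horizontal marks, means). Photosystem and electron transport genes lay at 14.03 to 14.08 without and 11.45 to 11.60 with lincomycin at 24 h, and cell cycle genes at 8.55 to 8.65 and 7.78 to 8.06, the array apart not counted.

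Most probe sets called in both treatments moved the same way. In both treatments 249 rose and 132 fell at 0.5 h (43 and 33 within batches). The numbers were 397 and 227 at 1 h (281 and 171) and 1910 and 2031 at 4 h (1845 and 1893). At 24 h they were 1885 and 2293 (1859 and 2324). The responses of the treatments correlated across probe sets, which are not independent replicates, with Pearson's r of 0.421 at 0.5 h, 0.511 at 1 h, 0.613 at 4 h and 0.371 at 24 h. Within batches, where the array apart is left out too, r was 0.105, 0.251, 0.488 and 0.394 at these times. Leaving out that array alone gave 0.5 at 24 h, so r was lower within batches at 24 h as well. The difference between the 0 h sets, which enters both responses, itself correlated between the treatments across probe sets (r = 0.548). Probe sets that moved in opposite directions, past the threshold in each treatment and in the difference, numbered 14, 13, 94 and 708 at 0.5, 1, 4 and 24 h. Within batches the numbers were 1, 7, 160 and 769, and without the array apart 62, 61, 242 and 840. Of the opposite responses at 24 h, 438 rose without and fell with lincomycin, and 270 did the reverse.

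Genes fixed in advance followed different courses (log2 signal, mean ± SD, n = 8 at 0 h and 4 at the later times named here). ELIP1 went from 6.14 ± 0.50 at 0 h to 11.24 ± 0.26 at 4 h without lincomycin, and from 6.72 ± 0.48 to 12.41 ± 0.06 with it. CHS went from 7.80 ± 1.06 to 13.21 ± 0.14 without and from 9.61 ± 1.14 to 13.95 ± 0.03 with lincomycin. GLK1 was at 8.42 ± 0.65 and 9.47 ± 0.65 without lincomycin at 0 and 24 h, and at 7.08 ± 0.54 and 6.72 ± 0.36 with it. The antenna gene LHCB5 stood at 15.08 ± 0.30 without and 12.97 ± 0.09 with lincomycin at 24 h. From 0 to 24 h LHCB5 (AT4G10340, 0.73 ± 0.09, within batches 0.38 ± 0.09) rose without lincomycin, and LHCB5 (-0.31 ± 0.09) fell with it.

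**Figure D3:**
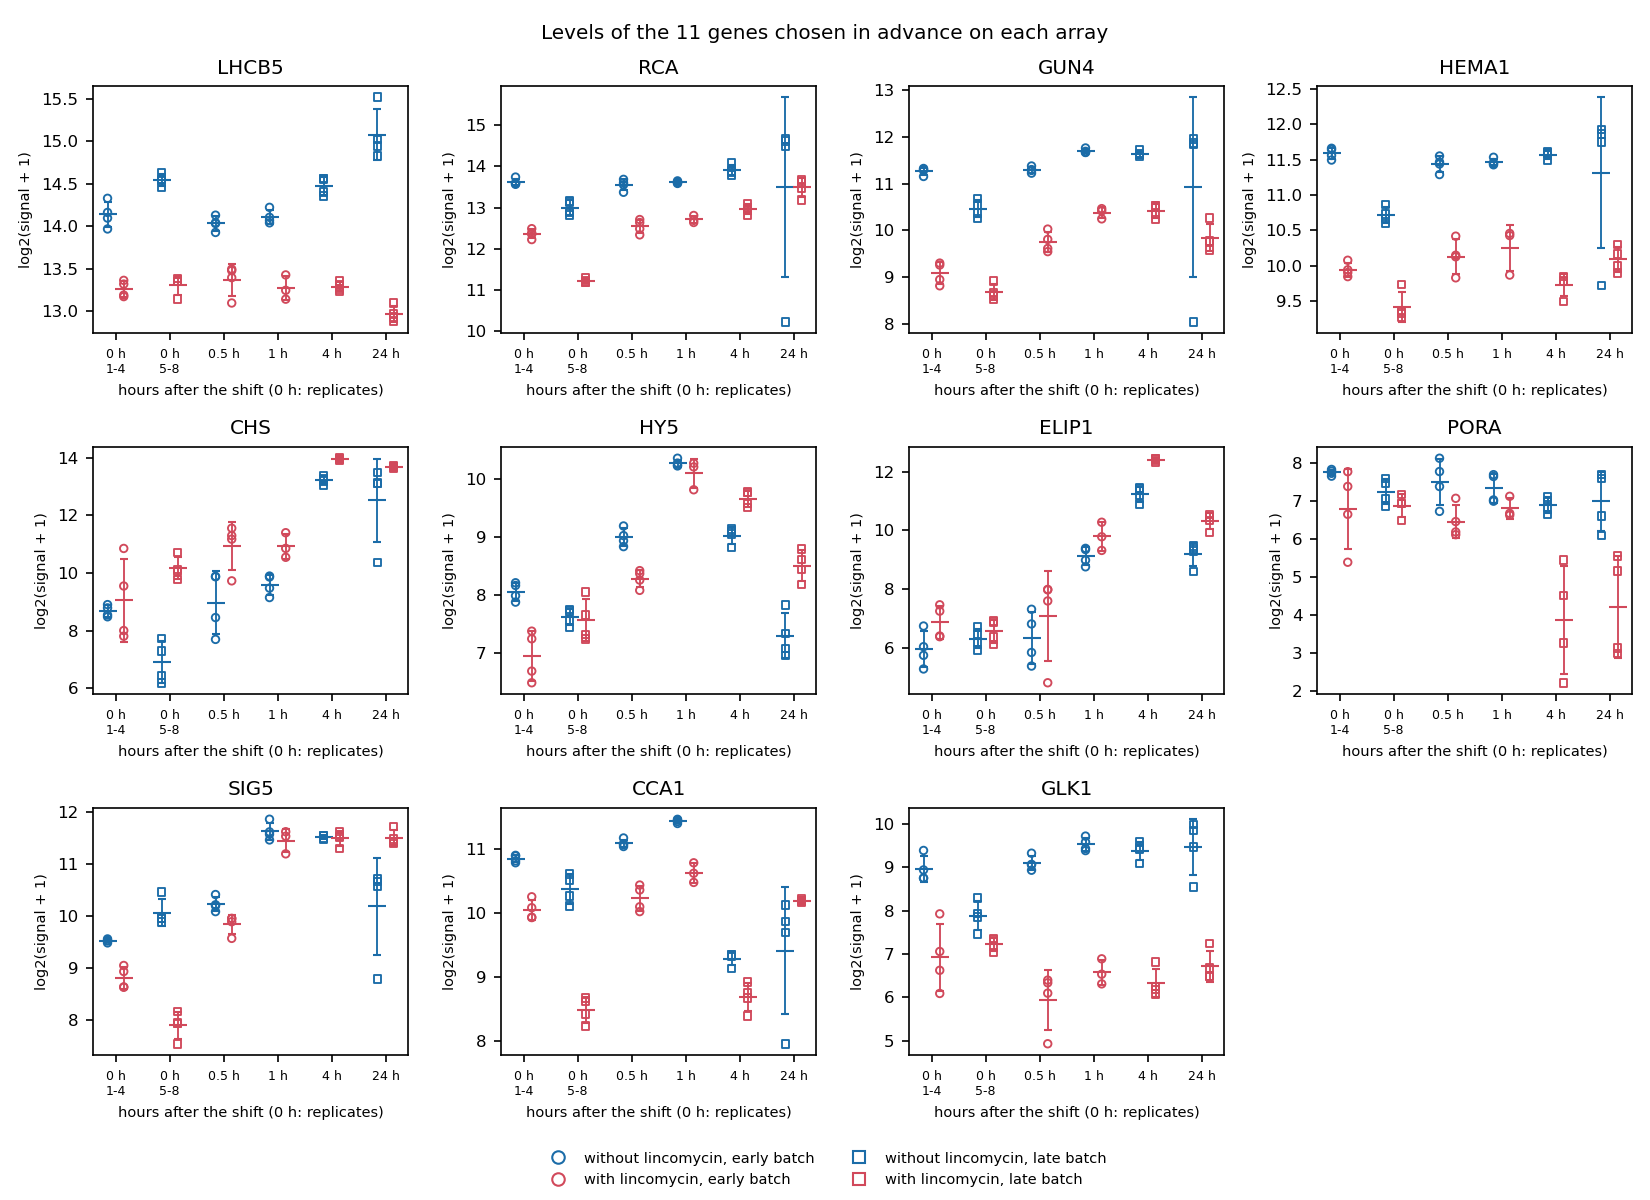
Log2 signal of each fixed gene on each array by time point, with 0 h numbers 1-4 and 5-8 apart (circles, early batches; squares, late batch; blue without and red with lincomycin; marks and bars, mean and SD). ELIP1 averaged 11.24 without and 12.41 with lincomycin at 4 h.

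**Figure D4:**
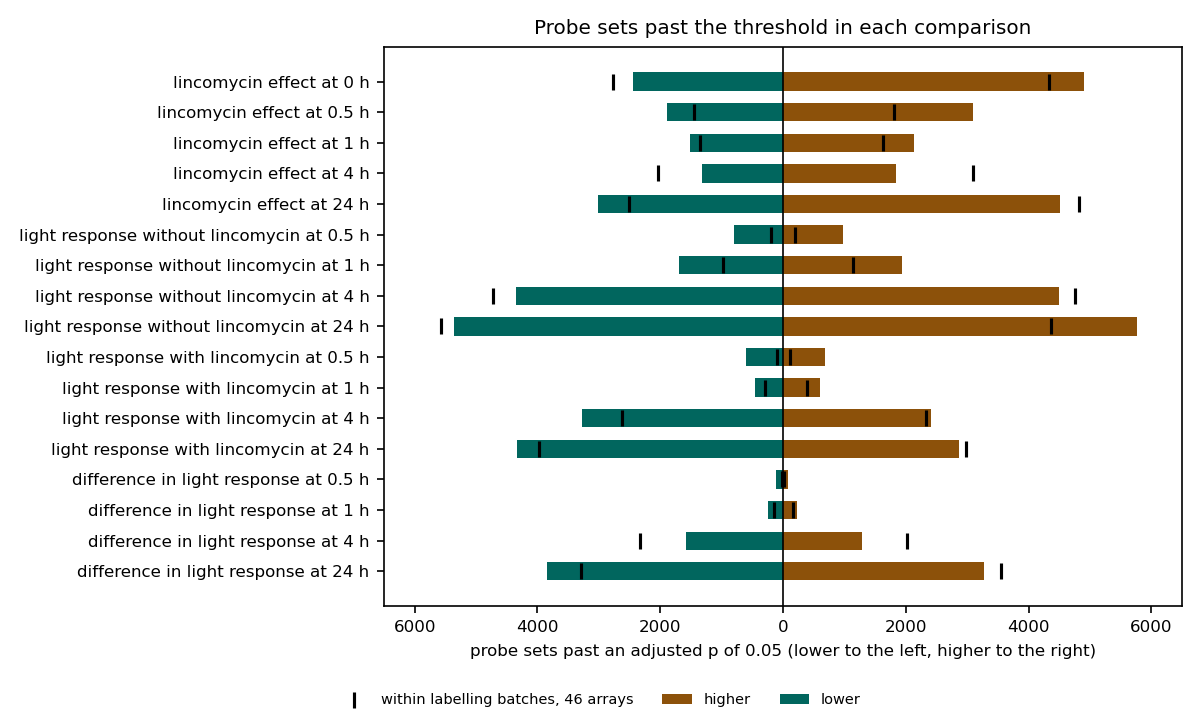
Number of probe sets past an adjusted p of 0.05 in each comparison, higher to the right and lower to the left, with ticks for the numbers within labelling batches. Counts ran from 196 for the difference at 0.5 h to 11117 for the response at 24 h without lincomycin.

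The table deposited by the authors gave log ratios (base and normalization not stated, read as log2) and p-values for 11 of these comparisons. Across 20396 probe sets, which are not independent replicates, its ratios correlated with the changes above with r of 0.298, 0.517, 0.778 and 0.84 for the response without lincomycin at 0.5, 1, 4 and 24 h. With lincomycin r was 0.217, 0.353, 0.655 and 0.707, and for the lincomycin effect at 0, 4 and 24 h it was 0.714, 0.67 and 0.788. With the changes within batches r was 0.418, 0.617, 0.825 and 0.778 without lincomycin, 0.326, 0.473, 0.724 and 0.769 with it, and 0.728, 0.67 and 0.657 for the lincomycin effect. For probe sets that changed by more than 2 within batches, the median ratio of deposited to own values was 1.13 at 4 h without lincomycin (522 probe sets). It was 0.02 at 0.5 h with lincomycin (13 probe sets), and for the lincomycin effect 0.44 at 0 h (250), 0.19 at 4 h (192) and 0.76 at 24 h (447). In the deposited table CHS changed by 7.95 and ELIP1 by 6.49 at 4 h without lincomycin, and SIG5 by -2.96 for lincomycin at 0 h. PORA, which fell by the tests above, had deposited ratios of -0.35 for lincomycin at 4 h, and -0.11 and -0.05 at 4 and 24 h with lincomycin. Without lincomycin its deposited ratios were -0.8 and -0.49 at 4 and 24 h. The deposited fall was thus larger without lincomycin, opposite in direction to the differences found for PORA here.

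Among the gene results given for the lincomycin effect, 72 of 77 had every array of one group above every array of the other. The number was 53 of 56 for the light response of either treatment. Chance gives such a separation for 0.016% of genes with 8 against 8 arrays, 0.404% with 8 against 4, 1.212% with 8 against 3, 2.857% with 4 against 4 and 5.714% with 4 against 3, and lack of overlap was part of the rule for the genes of largest change. Of 425 list tests, 210 passed the threshold, 119 higher and 91 lower, of which 107 held with an estimated correlation and 168 within batches.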

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

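The tests of degraded RNA, of a mislabelled sample, of a labelling batch between the 0 h sets and of the time of day were chosen only after the result was seen. In 135 tests, each of 1 measure or gene within 1 group of arrays, 14 values lay far from the rest of their group. Chance gives about 1 in 20 such tests, but values of the same array are not independent. Of the 14 values, 9 came from array 4 at 24 h without lincomycin. On that array the median signal was 293.9 (others 179.4 to 188), the median rank correlation 0.618 (0.915 to 0.917), the spike-in control Dap 4.83 (8.11 to 8.37) and the hybridization control Cre 16.14 (14.03 to 14.17). Log2 signals there were 10.22 for RCA (14.49 to 14.66), 8.04 for GUN4 (11.84 to 11.96), 9.72 for HEMA1 (11.75 to 11.93), 10.37 for CHS (13.1 to 13.49) and 8.8 for SIG5 (10.57 to 10.72). The other 5 were ELIP1 on array 1 at 0.5 h with lincomycin (4.81, others 7.6 to 7.99), SIG5 on array 4 of that group (9.58, others 9.9 to 9.96), HEMA1 on array 1 (11.49, others 11.59 to 11.61) and CCA1 on array 4 (9.13, others 9.32 to 9.35) at 4 h without lincomycin, and the median signal of array 2 at 4 h with lincomycin (217.4, others 211.4 to 212.3).

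Array 4 at 24 h without lincomycin was weighed first. Its highest rank correlation with any other array was 0.696, below the 0.956 that every other array reached, which argues against an intact sample of another group under a wrong label as the whole cause. Its GAPDH control read 3.17 log2 units higher at the 3' than at the 5' end, against -0.17 to 0.65 on the other arrays, so degraded RNA or a short labelled target may explain it. A wrong label on a degraded sample stays open, since such an array would correlate poorly with every group and its Dap of 4.83 lay near the mean of 4.31 of the early arrays without lincomycin. Which step failed also stays open, and no biological explanation was tested because the design gives none for 1 array.

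Within each treatment the 0 h arrays 5 to 8 differed from 1 to 4 in 5544 probe sets without and 4446 with lincomycin, or 8097 and 7187 without the array apart. The actin control rose by 1.21 log2 units more from the 5' to the 3' end in numbers 5 to 8 without lincomycin (1.95 to 2.25, against 0.77 to 0.91) and by 0.73 with it (1.6 to 2.02, against 1.02 to 1.19), which is consistent with a batch in labelling or target length. For the time of day, the absolute difference of the clock list between sets lay at percentile 72.9 of 10000 random lists without lincomycin and at percentile 100 with it, and 9 and 13 of its 16 genes were called. Time of day therefore cannot be told apart from other differences between the sets, because the treatments gave unlike answers and the harvest times are not known. The poly-A control Dap, which was not tested but helped to define the batches, averaged 9.04 on the early arrays with lincomycin.

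The lincomycin effects at 0.5 and 1 h compare arrays of different batches. The lincomycin effect at 0 h differed between the sets in 1160 probe sets with 47 arrays, between the bounds fixed before the test as shares of the 4987 called at 0.5 h, so batch and lincomycin cannot be told apart for these. With 46 arrays it differed in 2934, above the upper bound for the 7366 called then, which would have pointed to the batch. Of the probe sets called at 0.5 h, 83.3% had the same sign in the 0 h arrays compared within 1 batch, and at 1 h 83.5%, which is in line with an effect of lincomycin in the direction of most of them. What stays open is the size of each effect at 0.5 and 1 h.

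The light responses differed between the treatments, by the test of the difference itself, in 196, 477, 2869 and 7118 probe sets at 0.5, 1, 4 and 24 h. Within batches the counts were 42, 306, 4346 and 6844. Of the fixed genes, differences at 0.5 h were found for GLK1 (-1.81 ± 0.36, within batches -1.12 ± 0.39, not called), and at 1 h for GLK1 (-1.60 ± 0.38, within batches -0.92 ± 0.40, not called) and SIG5 (1.26 ± 0.29, within batches 0.53 ± 0.18, not called). Without array 2 at 1 h with lincomycin the 1 h values were -1.47 and 1.17, not called. At 1 h GUN4 (0.66 ± 0.52, within batches 0.87 ± 0.17) and HY5 (0.40 ± 0.23, within batches 0.93 ± 0.24) were called within batches but not with all arrays. At 4 h they were found for HY5 (1.21 ± 0.22, within batches 0.68 ± 0.23), PORA (-2.36 ± 0.63), SIG5 (1.42 ± 0.28, within batches 2.15 ± 0.18) and GLK1 (-1.70 ± 0.36). Called only within batches were CCA1 (0.74 ± 0.28, within batches 1.29 ± 0.16), CHS (-1.08 ± 0.65 and -2.52 ± 0.64), RCA (0.58 ± 0.55 and 0.84 ± 0.14), GUN4 (0.75 ± 0.50 and 0.55 ± 0.17) and HEMA1 (-0.37 ± 0.30 and -0.55 ± 0.16). At 24 h they were found for LHCB5 (-1.05 ± 0.13), HY5 (1.78 ± 0.22), PORA (-2.12 ± 0.63), SIG5 (2.76 ± 0.28), CCA1 (2.12 ± 0.28) and GLK1 (-1.39 ± 0.36, within batches -2.38 ± 0.40). Within batches CHS (-0.66 ± 0.65, within batches -2.81 ± 0.67) and HEMA1 (0.24 ± 0.30, within batches -0.46 ± 0.17) were called as well, HEMA1 with the opposite sign. RCA also differed at 24 h (1.51 ± 0.55). The value was 0.42 and still called without array 4 at 24 h without lincomycin, while its call was lost without array 1, 2 or 3 at 24 h with lincomycin (1.52, 1.47 and 1.45). PORA was dim with lincomycin at 4 and 24 h, so the sizes of its differences are uncertain.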

How the results depend on the processing

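Leaving out the array apart and the labelling batch as a block were chosen only after the data were seen. Counts that moved by more than 1.5 times are given by setting, and the cause was not tested. With 0 h numbers 1 to 4 alone the counts were for the response without lincomycin 164 and 1147 at 0.5 and 1 h, the response with lincomycin 64 and 286 at 0.5 and 1 h, the difference 14 and 64 at 0.5 and 1 h, opposite responses 0 and 2 at 0.5 and 1 h. With 0 h numbers 5 to 8 alone they were for lincomycin 4743 at 0 h, the response without lincomycin 5487 and 6669 at 0.5 and 1 h, the response with lincomycin 4752, 3743 and 2860 at 0.5, 1 and 4 h, the difference 1215 and 1313 at 0.5 and 1 h, opposite responses 132, 104 and 49 at 0.5, 1 and 4 h. With all 8 arrays at 0 h as 1 group they were for the response without lincomycin 373 and 2218 at 0.5 and 1 h, the response with lincomycin 177 and 387 at 0.5 and 1 h, the difference 48 and 158 at 0.5 and 1 h, opposite responses 0, 1 and 44 at 0.5, 1 and 4 h. After quantile normalization they were for the difference 286 at 1 h, opposite responses 9 at 0.5 h. Without dim probe sets they were for the difference 331 at 0.5 h, opposite responses 23 and 21 at 0.5 and 1 h. With 46 arrays they were for lincomycin 5768 and 5143 at 1 and 4 h, the response without lincomycin 3695 and 5962 at 0.5 and 1 h, the response with lincomycin 3108 and 2546 at 0.5 and 1 h, the difference 891, 1217 and 4859 at 0.5, 1 and 4 h, opposite responses 62, 61 and 242 at 0.5, 1 and 4 h. With the labelling batch as a block and 47 arrays they were for lincomycin 1585 and 1329 at 0.5 and 1 h, the response without lincomycin 194 and 1292 at 0.5 and 1 h, the response with lincomycin 79, 342 and 3075 at 0.5, 1 and 4 h, the difference 16 and 88 at 0.5 and 1 h, opposite responses 0, 2 and 53 at 0.5, 1 and 4 h. With the labelling batch as a block and 46 arrays they were for lincomycin 3251 and 5143 at 0.5 and 4 h, the response without lincomycin 399 and 2108 at 0.5 and 1 h, the response with lincomycin 206 and 675 at 0.5 and 1 h, the difference 42, 306 and 4346 at 0.5, 1 and 4 h, opposite responses 1, 7 and 160 at 0.5, 1 and 4 h. In fits of only the arrays of the groups compared they were for lincomycin 1574 at 24 h, the response without lincomycin 3151 and 5653 at 0.5 and 1 h, the difference 410, 869 and 4647 at 0.5, 1 and 4 h. With the replicate number as a block they were for lincomycin 2695, 0, 2057 and 64 at 0.5, 1, 4 and 24 h, the response without lincomycin 1, 508 and 2463 at 0.5, 1 and 24 h, the response with lincomycin 0 and 0 at 0.5 and 1 h, the difference 18, 140 and 3984 at 0.5, 1 and 24 h. Counts of 0 came from limma: at an unadjusted p under 0.05 the replicate block gave 5134 for lincomycin at 1 h and 1182 and 1796 for the response with lincomycin at 0.5 and 1 h, and the opposite responses at 0.5 h numbered 44 with numbers 1 to 4, 71 with all 8 as 1 group and 57 with the batch as a block. The labels do not say that replicate numbers pair arrays. Residuals of arrays of the same number correlated by -0.14 to 0.31 across probe sets, which are not independent replicates, and in none of the comparisons of groups did all exceed 0.1. Over 0.1 were 2 of 8 pairs at 0 h between treatments, 2 of 4 between 0 and 0.5 h without lincomycin, and 1 of 4 and 1 of 3 between 0 h and 0.5 or 1 h with it. Between 0 and 1 h with lincomycin 3 of 3 arrays correlated best with their own number (mean 0.15, others -0.02), a hint from the data that leaves sharing open. Of 425 list tests 210 passed the threshold, and 107 did with an estimated correlation, 235 with fry, 214 after quantile normalization and 205 with the batch block and 46 arrays. Of the 210, 168 also passed in the last of these with the same direction. Leaving out 1 array at a time gave 1004 to 1695 for the response without lincomycin at 0.5 h, 710 to 1420 for the response with lincomycin at 0.5 h, 593 to 1193 for the response with lincomycin at 1 h, 103 to 237 for the difference at 0.5 h, 298 to 516 for the difference at 1 h.

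Of 251 gene results given, 235 were called, 79 of these lost the call under 1 or more of the alternatives and 4 when 1 array was left out, and 1 changed sign with a call in either fit (HEMA1 in the difference at 24 h, -0.46 with the batch as a block and 46 arrays). The replicate block ended 69 calls, numbers 1 to 4 alone 14, numbers 5 to 8 alone 4, all 8 as 1 group 4, the batch block 12 with 47 and 9 with 46 arrays, only the arrays compared 5 and quantile normalization 3. Calls were gained with numbers 5 to 8 alone (3), 46 arrays (10), the batch block (5, and 14 with 46 arrays), only the arrays compared (8), the replicate block (4), dim probe sets left out (2) and 32 added to the signal (1). For list shifts, 12 calls were lost and 0 turned under quantile normalization. Signals near the background limit what changes could be found.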

Other observations

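The regroupings with the main effects removed and those that follow the 0 h sets were chosen only after the result was seen. For each comparison its arrays were also split in other ways into groups of the same sizes, with 100 splits, or all 35 for lincomycin from 0.5 to 24 h, the real split included. The real count was matched by 1 split, itself, for lincomycin at each time, with real and highest other counts of 7347 and 4247 at 0 h, 4987 and 217 at 0.5 h, 3649 and 1448 at 1 h, 3155 and 3 at 4 h and 7532 and 3591 at 24 h. The same held for the response without lincomycin, with 1775 and 1721 at 0.5 h, 3629 and 2295 at 1 h, 8853 and 4870 at 4 h and 11117 and 7499 at 24 h, and with lincomycin, with 1290 and 1210 at 0.5 h, 5693 and 2857 at 4 h and 7201 and 6862 at 24 h. At 1 h with lincomycin 4 of 100 splits gave as many (1062 and 3198), and a count several times the real one points to a structure of the samples. Few of the splits drawn gave as many for these comparisons, though for some, as both light responses at 0.5 h, another came close. Many splits also cross the labelling batches, so they exclude neither chance nor a batch difference. For the differences 1 of 100 splits gave as many at 4 h (2869 and 1099) and 24 h (7118 and 4864) and 2 at 0.5 h (196 and 322). Few splits thus gave as many at these times, which alone does not exclude chance. At 1 h 5 of 100 did (477 and 3824), so chance cannot be excluded, and the high count again points to a structure of the samples. With the main effects removed, 1 of 100 splits gave as many at 1 h, and the highest other count was 220.

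Splits that followed the labelling batches gave large counts, so the 0 h sets form a structure of their own. Setting 0 h numbers 5 to 8 in the place of the later time gave 7217 and 7617 probe sets for 0.5 and 1 h without lincomycin, and 6285 and 5768 with it, more than the real counts. Setting numbers 1 to 4 in that place gave 7484 and 7553 for 4 and 24 h with lincomycin, more than the real splits. Within 1 batch the real and the highest other of 35 splits were 194 and 2 at 0.5 h, 1292 and 2 at 1 h, 7626 and 439 at 4 h and 9602 and 5782 at 24 h without lincomycin, and 79 and 65, 342 and 146, 3075 and 20 and 5077 and 6 with it. Between the 0 h sets some lists moved unequally in the treatments, which was not tested. Others moved alike, as root markers (median -0.53 without and -0.52 with lincomycin). Of 28 mitochondrial genome genes 19 were higher in numbers 5 to 8 without lincomycin (median 0.97), and 7 higher and 1 lower with it (0.11). Of 16 clock genes 3 were higher and 6 lower without it (-0.19), and 2 and 11 with it (-0.70). Of 27 plastid ribosome genes 1 was higher and 19 lower without it (-0.45), and 6 and 5 with it (0.05).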
